A study of Arabidopsis thaliana with 2 samples.

How the data were processed

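Chromatin immunoprecipitation with sequencing (ChIP-seq), which sequences the DNA fragments recovered with an antibody against a chromatin protein, was done on roots of Arabidopsis thaliana plants carrying TGA1 fused to green fluorescent protein (TGA1-GFP). TGA1 is a bZIP transcription factor of the TGA family. Per the labels' protocols, roots were cross-linked with 1% formaldehyde, chromatin from sonicated nuclei was isolated with GFP antibodies, and libraries were made from 100 ng of DNA. The titles name 1 library from the GFP antibody and 1 from IgG, an antibody with no specified target that gives the background, so each group held 1 library and no replicate. Per the submitters' processing notes, Bowtie2 and MACS2 were used with the TAIR10 build. Their versions, the thresholds, any filter and whether the IgG library served as the control in peak calling are not given in the sources used here.

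The deposited file was 1 list of peaks for the whole series with 3 columns: chromosome, start and end. It had no header and no height, fold enrichment, p-value, q-value or summit, and its entries were not in order of position. No read counts were given, so the depth of both libraries is unknown and no counting interval can be put on a peak. Starts were read by the BED convention and are printed counted from 1; if the authors' starts already counted from 1, each is off by 1 base. Peak width (end minus start) and the place of a peak in the list were the measures left to describe peaks, and the midpoint stood for the summit.

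Genes were taken from a RefSeq gene table of assembly TAIR10.1, which differs from TAIR10 in the organelle genomes and keeps the nuclear chromosomes. As a check of the shared coordinates, all peaks were shifted along the chromosomes. On each of the 5 chromosomes the share of midpoints inside protein-coding genes was lowest with no shift (24.4 to 27.8%) and rose to between 59.0 and 64.3% at shifts of 5000 bp. The table holds 37887 genes on these chromosomes, of which 27432 are protein-coding. It gives no strand, exons or UTRs, so the start of a gene could not be told from its end, and a zone at both ends replaced the planned promoter: a gene was assigned a peak when the midpoint lay from 1000 bp outside to 200 bp inside either end. Since no genome sequence was used here, the planned tests of the TGACG motif, of 6-mers and of motif against peak strength were not run.

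Positions were compared with 1000 random placements of the peaks on their own chromosomes with widths kept, using two-sided permutation p-values adjusted over 4 feature classes. The 14 gene sets were fixed before the data were examined and hold 230 genes, of which 229 are in the gene table. The table pairs 194 of them with the name used here. The other 35 carry the name of the fixed set and are printed with their locus tags. Members with a peak were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 14 sets. The same test was run on 178 families of gene names that share a letter stem and have at least 10 members. Both were repeated against 10000 random sets matched on the length of gene-free sequence on both sides of the gene, in 20 bins; 0.0002 is the smallest two-sided p these can give. The threshold was an adjusted p of 0.05. Intervals on shares are 95% Wilson intervals over genes or peaks. Genes and peaks are not replicates, and all p-values describe this 1 peak list, not repeat experiments.

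Genes were named by a rule fixed before the data were examined: in each set up to 6 members with a peak, and 13 genes whatever they showed (TGA1, TGA4, NRT2.1, NRT2.2, NRT2.4, NRT3.1, NIA1, NIR1, CEPD1, CEPD2, CEPDL2, CEPH and CPC). The rule also named the 15 peaks of highest peak value. With no peak value in the file, width took its place in both parts, and the first 15 peaks of the list were added after the data were examined. Other genes named here were chosen after their values were seen. Alternatives were other zones (500 and 2000 bp, nearest gene end, whole gene), other overlap rules, other placements, and protein-coding genes alone as annotation. Added after the data were examined were the wider and the earlier of 2 equal parts of the peaks, any overlap of a peak with the zones, placements within the own 1 Mb bin and the salicylic acid set without WRKY genes. A list of 23 cytosolic ribosomal protein genes was also written after the data were examined. Code was tested on simulated data. Over 10 rounds on 27432 genes with 20 families in which 60% of members were hit, Fisher's exact test recovered 69.5% of them with 0.4 false calls per round, and the matched test 57.0% with 0.1. Each simulated gene was hit independently, so these rates do not cover peaks shared by neighbouring genes, which the real list holds. A simulated flank share of 62.4% of 8002 peaks came out as 62.2%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.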

Results

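ChIP-seq with a GFP antibody addresses where TGA1-GFP sits on the genome of roots. The data were 1 list of 8002 peaks from roots of TGA1-GFP plants, for which 1 library from a GFP antibody and 1 from IgG were labelled. The peaks had a median width of 434 bp (quartiles 334 and 625 bp, range 249 to 4997 bp) and covered 4.40 Mb, or 3.69% of the 5 nuclear chromosomes. With 1 library per antibody there was no replicate, and the number of reads behind each peak is unknown. The list ran from wide to narrow peaks: the median width was 986 bp for the first 500 peaks and 286 bp for the last 500 (Spearman's rho of width and place -0.71, Pearson's r of log2 width and place -0.67, both across peaks, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The file does not say what the order stands for. A place in the list is therefore given below only as a place.

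TGA1-GFP peaks were dense in gene-rich parts of the chromosomes and sparse in 1 gene-poor inner stretch of each. Chromosome 1 held 2165 peaks (71.2 per Mb), chromosome 2 held 1278 (64.9 per Mb), chromosome 3 held 1523 (64.9 per Mb), chromosome 4 held 1239 (66.7 per Mb) and chromosome 5 held 1797 (66.6 per Mb). Among full bins the most crowded 1 Mb held 133 peaks, on chromosome 4, and the emptiest held 0, on chromosome 3, against a median of 72 over 116 full bins. The 13 bins with 10 or fewer peaks had a median of 33 protein-coding genes, against 260 over all bins. Across bins, which are not independent replicates, peaks and genes rose together (Pearson's r = 0.84, Spearman's rho = 0.73, permutation p = 1e-05 for both; r = 0.83 without the 2 bins farthest from the median number of genes).

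**Figure D1:**
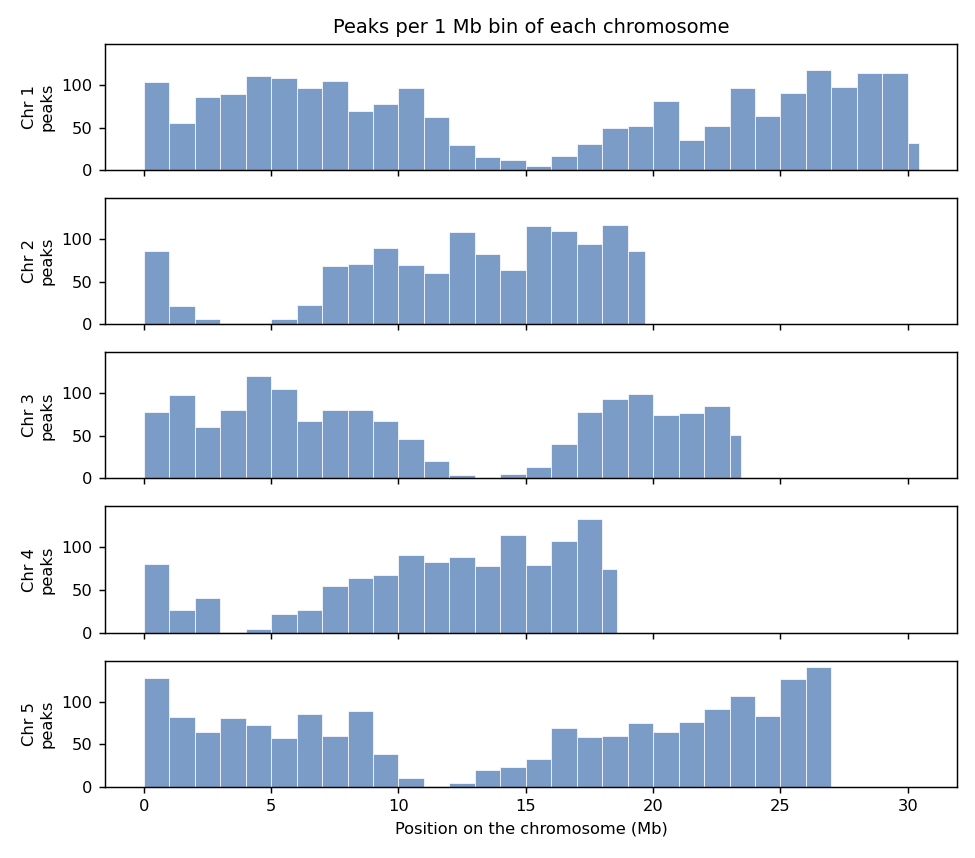
Number of TGA1-GFP peaks (vertical axis) in each 1 Mb bin along the 5 nuclear chromosomes (horizontal axis, Mb). Bars fall close to 0 in an inner stretch of each chromosome, and the last bar of each chromosome is a partial bin; the highest full bin holds 133 peaks, on chromosome 4.

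Most peaks had their midpoint just outside a gene. The midpoints of 4330 peaks, 54.1% (95% interval 53.0 to 55.2%), were outside any annotated gene and within 1000 bp of a gene end, 2.18 times the 24.8% ± 0.490 (SD over 1000 random placements) given by chance. Inside protein-coding genes lay 2022 midpoints, 25.3% (24.3 to 26.2%) against 54.2% ± 0.545 by chance, a ratio of 0.466. Many more peaks reached into a gene with an edge: 4268 peaks, 53.3%, overlapped a protein-coding gene by at least 1 bp, against 62.2% by chance, a ratio of 0.858. Inside other annotated genes, such as pseudogenes and non-coding RNA genes, lay 159 midpoints, 1.99% (1.7 to 2.32%) against 9.95% ± 0.330, a ratio of 0.20. That ratio was 0.46 when peaks were placed at random within their own 1 Mb bin, where chance gave 4.32%. All of these differences had an adjusted permutation p of 0.002, the smallest the placements can give. The remaining 1491 midpoints, 18.6% (17.8 to 19.5%), were more than 1000 bp from any gene, 1.68 times the chance share. That excess turned into a deficit, 0.89 times the chance share, when only protein-coding genes were counted as genes.

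The ratio to chance was highest close to the gene. Of the 5980 midpoints outside protein-coding genes, the median lay 486 bp from the nearest gene end. The bin from 100 to 200 bp outside held 851 midpoints against 232 expected, a ratio of 3.67. Of the first 2001 peaks of the list, 18.6% (16.9 to 20.4%) had midpoints inside a protein-coding gene, and of the last 2000 peaks 29.7% (27.7 to 31.7%); this difference was not tested. Without strand these distances join the flanks at the start and at the end of genes.

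**Figure D2:**
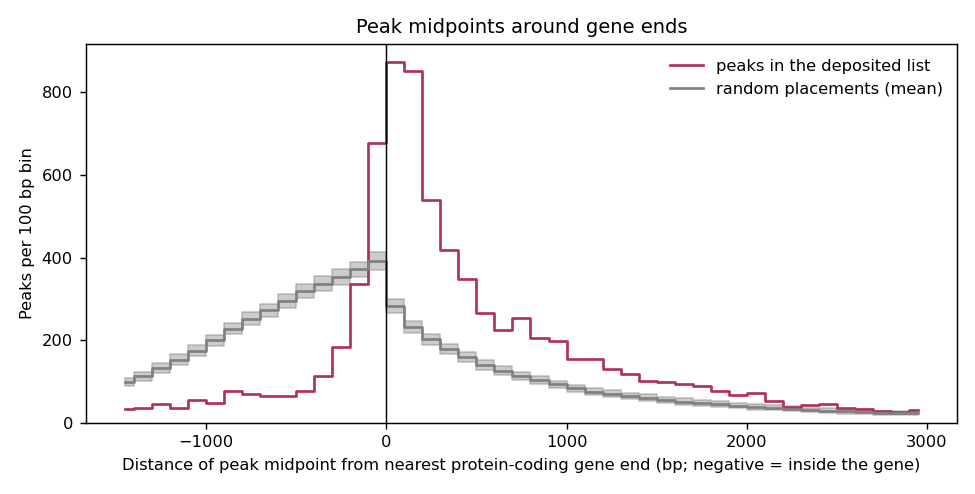
Number of peak midpoints per 100 bp bin (vertical axis) by distance from the nearest protein-coding gene end (horizontal axis, bp; negative values are inside the gene), for the deposited peaks and for the mean of 200 random placements with a band of 1 SD. The deposited peaks exceed chance most from 100 to 200 bp outside the gene, with 851 peaks against 232.

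A peak was assigned to 6262 of 27432 protein-coding genes, 22.8% (22.3 to 23.3%). Of these, 1034 genes had 2 or more peaks and 86 had 3 or more, with at most 4. Of the peaks, 3510 were assigned to 1 gene, 1899 to 2 or more genes and 2593 to none. A peak given below at a named gene can therefore also be assigned to a neighbour. This was so for BHLH39 (also EDA7), NAS1 (also SUVH1), NRT2.5 (also RSH2) and GSTF7 (also LPA1), among others. Widths at members of the gene sets are those of assigned peaks unless stated otherwise, and some genes had wider peaks nearby outside the zone. Genes with a peak had a median of 2230.5 bp of gene-free flanking sequence, and genes without one had 1737 bp. Comparisons of gene sets were therefore repeated against random sets matched on this length.

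The nitrogen regulators were among the most frequently marked gene sets. Of 23 fixed nitrogen response regulators, 15 carried a peak, 65.2% (44.9 to 81.2%) against 22.8% of other genes (odds ratio 6.35, p = 1.7e-05, adjusted p = 0.000119, Fisher's exact test). Random sets matched on flank length gave 5.89 ± 2.1 genes (SD), and the set passed the threshold against them in that permutation test (adjusted p = 0.0028) and under all 8 alternatives (adjusted p 2.65e-06 to 0.0028). HRS1 (AT1G13300), HHO2 (AT1G68670) and HHO3 (AT1G25550), transcriptional repressors of the nitrate starvation response, had 2 peaks each. The widest at HRS1 was 2118 bp (chromosome 1, 4558450 to 4560567, TAIR10) with its midpoint 715 bp from the gene, and the one at HHO3 was 1087 bp wide, with its midpoint 170 bp from the gene, at place 81 of the list. NLP7 (AT4G24020), a master regulator of the primary nitrate response, had a 1697 bp peak with its midpoint 601 bp away. LBD38 (AT3G49940), a repressor of nitrate-responsive genes, had 2 assigned peaks, the widest 1174 bp. AFB3 (AT1G12820), an auxin receptor that responds to nitrate, had a 948 bp peak with its midpoint 285 bp away. CEPH (AT4G32950), a phosphatase that acts on the nitrate transporter NRT2.1, had 1 assigned peak of 444 bp, which was also assigned to GAMMA-VPE. A peak of 884 bp at place 3232 had its midpoint inside the gene, 238 bp from the gene end and outside the zone. A wider one of 1967 bp at place 89 (chromosome 4, 15906214 to 15908180) had its midpoint 1098 bp from the gene, just beyond the zone.

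In the set of nitrate uptake and reduction, NRT2.1 and NRT3.1 carried peaks early in the list. NRT2.1 (AT1G08090), the main high-affinity nitrate transporter of roots, had a 1943 bp peak at place 33 (chromosome 1, 2522201 to 2524143) with its midpoint 851 bp outside the gene. NRT3.1 (AT5G50200), its partner protein, had a 1478 bp peak at place 18 (chromosome 5, 20437384 to 20438861) with its midpoint 307 bp outside the gene and another of 597 bp with its midpoint inside it. At NRT2.2 (AT1G08100), the neighbour of NRT2.1, a 1085 bp peak at place 60 (chromosome 1, 2529903 to 2530987) had its midpoint 1325 bp away, outside the zone. Among the other NRT2 genes, NRT2.5 (AT1G12940) had a 420 bp peak at place 4401 and NRT2.6 (AT3G45060) a 319 bp peak at place 5406. NRT2.3 (AT5G60780), NRT2.4 (AT5G60770) and NRT2.7 (AT5G14570) had no midpoint within 3000 bp; the nearest midpoint to NRT2.4 was 7382 bp away. The nitrate reductase genes NIA1 (AT1G77760) and NIA2 (AT1G37130) had 2 assigned peaks each, the widest 496 and 550 bp. Near NIA1, wider peaks of 916 bp at place 248 and 1052 bp at place 1698 had midpoints 1573 and 1752 bp away. Near NIA2, wider peaks of 597 and 613 bp had midpoints 2069 and 1815 bp away. The zone did not assign these wider peaks. NRT1.1 (AT1G12110), the dual-affinity nitrate transporter and sensor, had a 440 bp peak, and the peak nearest to the nitrite reductase gene NIR1 (AT2G15620) was 499 bp wide with its midpoint 1159 bp away. As a set, 7 of 19 genes of nitrate uptake and reduction carried a peak, 36.8% (19.1 to 59.0%), which did not pass the threshold (odds ratio 1.97, adjusted p = 0.215, Fisher's exact test). Counting peaks inside the genes as well gave 11 of 19 and an adjusted p of 0.00552 by Fisher's exact test. Over the 8 alternatives adjusted p ran from 1.91e-06 to 0.698. Against random sets matched on flank length it was 0.333 (permutation test).

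**Figure D3:**
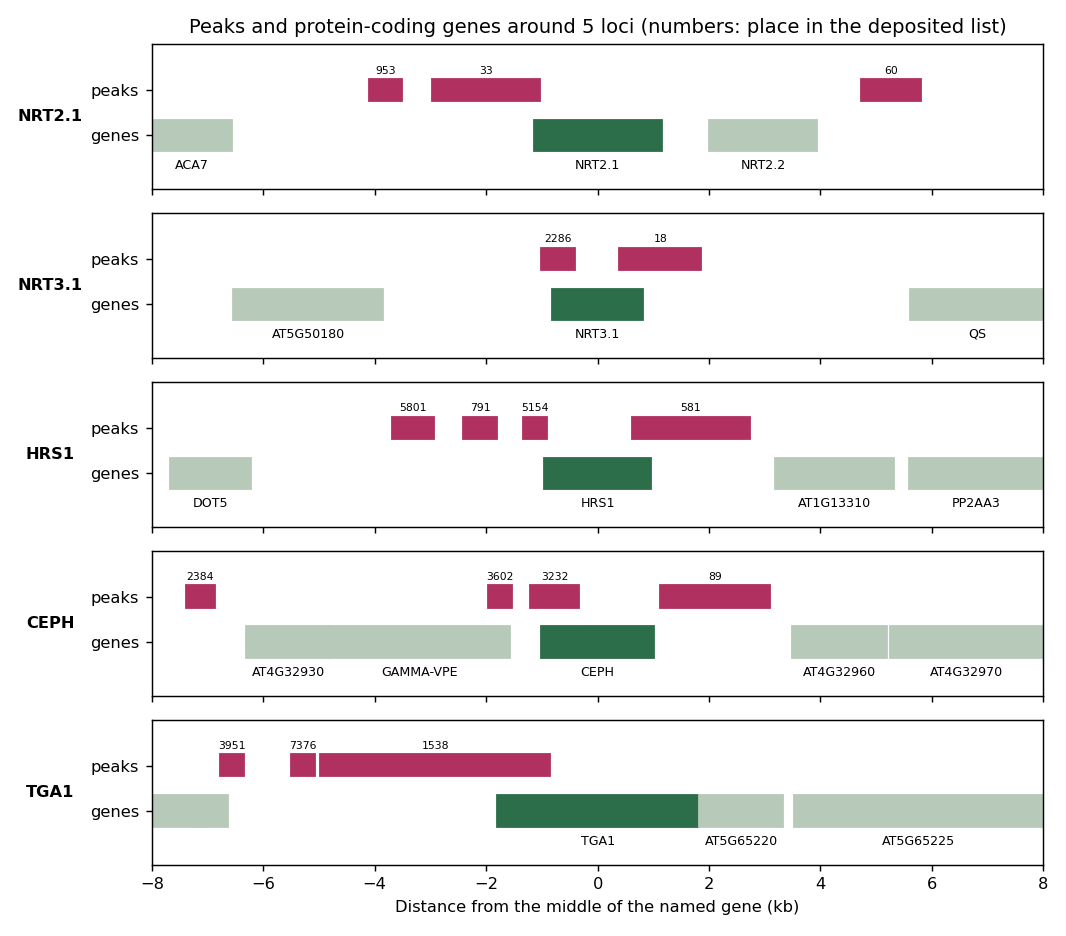
Peaks (upper boxes, with their place in the list) and protein-coding genes (lower boxes) around NRT2.1, NRT3.1, HRS1, CEPH and TGA1, by distance from the middle of the named gene (horizontal axis, kb). The peaks at places 33 and 60 flank the NRT2.1 and NRT2.2 pair, and the peak at TGA1, 4142 bp wide, reaches into the gene from one side.

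Of 16 genes of ammonium uptake and nitrogen assimilation, 8 carried a peak, 50% (28.0 to 72.0%; odds ratio 3.38, p = 0.0158, adjusted p = 0.0369, Fisher's exact test). The ammonium transporter genes AMT1;1 (AT4G13510), AMT1;3 (AT3G24300) and AMT1;5 (AT3G24290) had assigned peaks of 1560, 975 and 1426 bp, the last at place 47. Near AMT1;3 a wider 2416 bp peak at place 171 had its midpoint 1049 bp from the gene, outside the zone. The cytosolic glutamine synthetase genes GLN1;1 (AT5G37600), GLN1;2 (AT1G66200) and GLN1;3 (AT3G17820) had peaks of 727, 543 and 671 bp. Against random sets matched on flank length, which gave 4.23 ± 1.76 genes, the set did not pass the threshold in the permutation test (adjusted p = 0.18; 0.00101 to 0.18 over its 8 alternatives).

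TGA1 and its relatives were marked in part. The second widest peak of the list, 4142 bp at place 1538 (chromosome 5, 26054357 to 26058498), overlapped 966 bp of TGA1 (AT5G65210) and ran on for 3176 bp outside it; its midpoint was 1106 bp from the gene, so the zone did not assign it. TGA4 (AT5G10030), the closest relative of TGA1, had a 1557 bp peak inside the gene, with its midpoint 3144 bp from the nearer gene end. TGA3 (AT1G22070), TGA6 (AT3G12250), TGA7 (AT1G77920), TGA9 (AT1G08320) and TGA10 (AT5G06839) had assigned peaks, the widest 997 bp at TGA10. That made 5 of 10 genes (50%, 23.7 to 76.3%; odds ratio 3.38, adjusted p = 0.0967, Fisher's exact test). Adjusted p ran from 0.0138 to 0.186 over the 8 alternatives, 4 of which were past the threshold.

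The class III glutaredoxins carried peaks at about the share of other genes. These small redox proteins include CEPD1, CEPD2 and CEPDL2, the shoot-derived polypeptides that report the nitrogen demand of the shoot to the root. A peak was assigned to 5 of 21 genes, 23.8% (10.6 to 45.1%; odds ratio 1.06, adjusted p = 1, Fisher's exact test), and none of the 8 alternatives passed the threshold. GRXS13 (AT1G03850) had a 1785 bp peak at place 19, which was also within reach of PHB2. GRXC9 (AT1G28480), a partner of TGA factors in hormone crosstalk, had 2 peaks, 1 of them of 458 bp at place 230. GRXC6 (AT4G33040), GRXC8 (AT5G11930) and ROXY2 (AT5G14070) had peaks of 440, 525 and 341 bp. The nearest midpoints to CEPD1 (AT1G06830), CEPDL2 (AT2G47870) and CEPD2 (AT2G47880) were 5853, 3523 and 1892 bp away.

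Genes of the iron deficiency response carried many peaks. Of 22 genes, 15 had one, 68.2% (47.3 to 83.6%; odds ratio 7.26, p = 7.5e-06, adjusted p = 0.000105, Fisher's exact test), against 5.64 ± 2.06 in matched random sets, and the set passed the threshold under all 8 alternatives. FIT (AT2G28160), the transcription factor that drives iron uptake, had a 585 bp peak at place 180 with its midpoint 139 bp from the gene. BHLH39 (AT3G56980), its partner, had a 649 bp peak at place 36. PYE (AT3G47640), a regulator of iron homeostasis, had one of 764 bp, the nicotianamine synthase gene NAS1 (AT5G04950) one of 820 bp, and S8H (AT3G12900) and PDR9 (AT3G53480), which make and export coumarins, had peaks of 895 and 1307 bp. The phosphate starvation set had 6 of 12 genes with a peak (adjusted p = 0.0721) and the sulfur deficiency set 5 of 12 (adjusted p = 0.215, both Fisher's exact test), and neither passed the threshold. Among them the phosphate transporter genes PHT1;1 (AT5G43350) and PHT1;2 (AT5G43370) had peaks of 1716 and 801 bp, SPX1 (AT5G20150), SPX2 (AT2G26660), PHF1 (AT3G52190) and IPS1 (AT3G09922) had peaks of 679, 385, 532 and 375 bp, and the sulfur genes LSU1 (AT3G49580), SULTR2;1 (AT5G10180), APR3 (AT4G21990), SDI1 (AT5G48850) and SDI2 (AT1G04770) had peaks of 721, 520, 349, 343 and 327 bp. Each passed the threshold under some alternatives, 4 of 8 for phosphate (adjusted p 0.0227 to 1) and 3 of 8 for sulfur (0.000297 to 0.756).

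The set of glutathione transferases and chemical detoxification, made up mostly of glutathione transferase genes, carried peaks at most of its members. Of 18 genes, 12 carried a peak, 66.7% (43.7 to 83.7%; odds ratio 6.77, p = 8.99e-05, adjusted p = 0.00042, Fisher's exact test), against 4.19 ± 1.8 in matched sets, and all 8 alternatives passed the threshold. These were 11 of 14 glutathione transferase genes and 1 of 4 others, OPR1, a difference that was not tested. OPR3 (AT2G06050), CYP81D11 (AT3G28740) and UGT74E2 (AT1G05680) had none assigned. GSTU19 (AT1G78380) had a 1052 bp peak. GSTU24 (AT1G17170) and GSTU25 (AT1G17180) shared a 582 bp peak, GSTF7 (AT1G02920) had one of 592 bp, GSTU1 (AT2G29490) one of 453 bp and OPR1 (AT1G76680) one of 443 bp. GSTU1 and GSTU2 (AT2G29480) also shared a peak, as did GSTU6 (AT2G29440) and GSTU7 (AT2G29420). The 12 genes rested on 11 peaks, although GSTU1 and OPR1 had 2 assigned peaks each. Neither Fisher's exact test nor the matched sets allowed for this sharing, so their p-values overstate the evidence.

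Of 10 cytokinin type-A response regulators, 7 carried a peak, 70.0% (39.7 to 89.2%; odds ratio 7.90, p = 0.00199, adjusted p = 0.00696, Fisher's exact test), against 2.64 ± 1.41 in matched sets. These genes dampen cytokinin signalling. ARR4 (AT1G10470) had a 1963 bp peak, ARR7 (AT1G19050) one of 900 bp, and ARR6 (AT5G62920), ARR8 (AT2G41310), ARR9 (AT3G57040) and ARR17 (AT3G56380) had peaks of 403 to 560 bp. With only the earlier of 2 equal parts of the peak list the set did not pass the threshold (Fisher's exact test, odds ratio 3.12, adjusted p = 0.165; 0.00736 to 0.165 over the 8 alternatives).

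Of 27 genes of salicylic acid signalling and systemic immunity, 13 carried a peak, 48.1% (30.7 to 66.0%; odds ratio 3.14, p = 0.00429, adjusted p = 0.012, Fisher's exact test). NPR3 (AT5G45110), a salicylic acid receptor, had a 1734 bp peak, NIMIN1 (AT1G02450), which binds the immune regulator NPR1, a 665 bp peak at place 114, and the transcription factor genes WRKY70 (AT3G56400) and WRKY38 (AT5G22570) had peaks of 988 and 897 bp. DLO1 (AT4G10500) and DMR6 (AT5G24530), which encode enzymes that hydroxylate salicylic acid, had assigned peaks of 747 and 698 bp. At DMR6 a wider 1188 bp peak at place 88 had its midpoint inside the gene, outside the zone, 2069 bp from the gene end. All 6 WRKY genes of the set carried a peak, and without them 7 of 21 did, which did not pass the threshold (Fisher's exact test, adjusted p = 0.344). Over its 9 alternatives adjusted p ran from 7.18e-05 to 0.344.

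The remaining sets did not pass the threshold by Fisher's exact test. Of 9 root hair genes, 3 carried a peak (exact adjusted p = 0.469): RHD6 (AT1G66470), a 637 bp peak at place 130, EXPA7 (AT1G12560) and LRX1 (AT1G12040). CPC (AT2G46410), a root hair fate regulator, had its nearest midpoint 1708 bp away. Of 14 photosynthesis genes, markers of shoot tissue, 1 carried a peak (7.14%, 1.27 to 31.5%; exact adjusted p = 0.249), LHCA1 (AT3G54890). Of 16 abundantly transcribed housekeeping genes, 7 carried a peak (43.8%, 23.1 to 66.8%; odds ratio 2.63, exact adjusted p = 0.105), among them UBQ10 (AT4G05320), ACT2 (AT3G18780), GAPC1 (AT3G04120) and GAPC2 (AT1G13440) with peaks of 1063, 615, 718 and 527 bp, and UBQ11 (AT4G05050) and EF1A1 (AT1G07940) with peaks of 466 and 453 bp. The housekeeping set passed the threshold under 2 of 8 alternatives, with adjusted p from 0.0147 to 0.241.

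**Figure D4:**
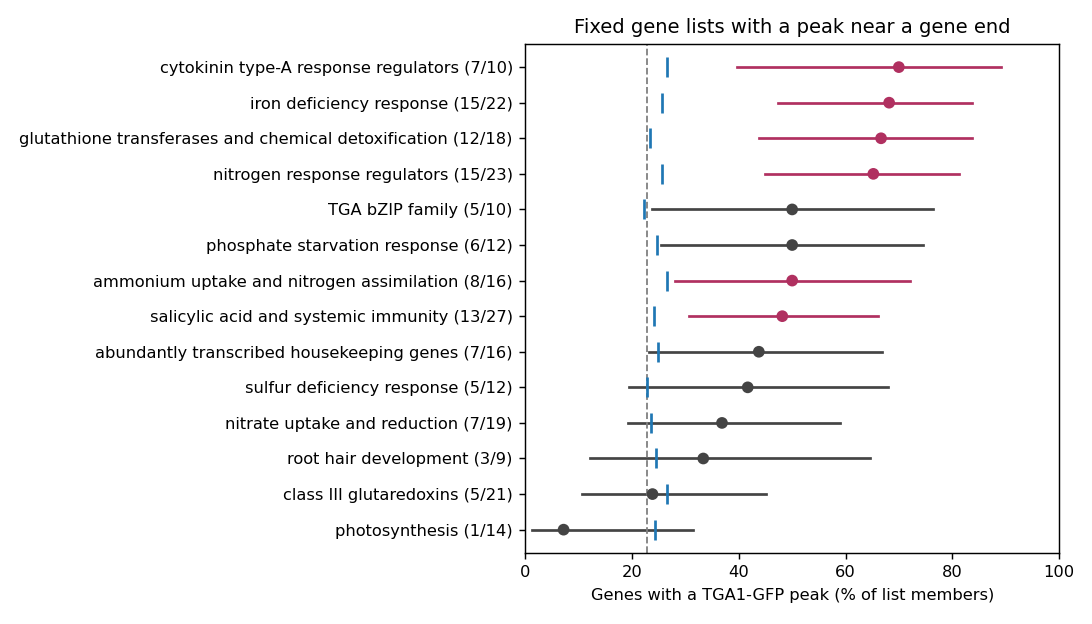
Share of the members of each fixed gene set with a TGA1-GFP peak (points, horizontal axis in percent) with 95% Wilson intervals; coloured points passed an adjusted p of 0.05. The dashed line is the 22.8% of all protein-coding genes, and the vertical ticks are the mean shares of random sets matched on flank length. Cytokinin, iron, glutathione transferase and nitrogen regulator sets lie between 65.2 and 70.0%.

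Over gene families defined by their names, 13 of 178 differed from all other genes by Fisher's exact test, 11 with more peaks and 2 with fewer. WRKY transcription factors had the lowest adjusted p: 41 of 67 genes, 61.2% (49.2 to 72.0%; odds ratio 5.36, exact adjusted p = 3.24e-09), carried a peak, among them WRKY11 (AT4G31550) with a 2536 bp peak and WRKY65 (AT1G29280) and WRKY17 (AT2G24570) with peaks of 1817 and 1773 bp. Other transcription factor families were bZIP (17 of 31, exact adjusted p = 0.00495), MYB (46 of 120, adjusted p = 0.00495) and NAC (31 of 79, adjusted p = 0.0194). Signalling families were the CIPK calcium-regulated kinases (13 of 21, exact adjusted p = 0.00495), MPK mitogen-activated kinases (10 of 18, adjusted p = 0.0363) and JAZ repressors of jasmonate signalling (7 of 10, adjusted p = 0.0295), with a 2371 bp peak at JAZ1 (AT1G19180) and a 1491 bp peak at JAZ3 (AT3G17860). Families of transferases and transporters were GSTU glutathione transferases (15 of 27 on 13 peaks, exact adjusted p = 0.00692), ABCC transporters (10 of 15, adjusted p = 0.00919) and UGT glycosyltransferases (24 of 58, adjusted p = 0.0246), with peaks of 1947 bp at ABCC5 (AT1G04120) and 1330 bp at UGT76B1 (AT3G11340). ABCC1 (AT1G30400) and ABCC12 (AT1G30410) shared a peak, as did UGT73B1 (AT4G34138) and UGT73B2 (AT4G34135), and the tests did not allow for such sharing. Many GSTU genes were also members of the fixed detoxification set, so these results are not separate. The ACR name family had 8 of 11 genes with a peak (exact adjusted p = 0.0122). Fewer peaks than elsewhere were found at EMB genes, named for embryo-defective mutants (13 of 160, 8.12%, exact adjusted p = 0.000142), and at LCR genes, which encode small cysteine-rich proteins (6 of 81, 7.41%, adjusted p = 0.0101). NAC, UGT, JAZ and MPK did not pass the threshold in permutation tests against random sets matched on flank length (adjusted p = 0.0876, 0.0615, 0.0876 and 0.137), whereas the other 9 did; over the 8 alternatives adjusted p ran from 0.0028 to 0.0876 for NAC, 0.000836 to 0.274 for UGT, 0.0374 to 0.979 for JAZ and 0.00881 to 0.774 for MPK. Of the other 9, WRKY passed under all 8 alternatives and ACR, CIPK and EMB under 7, with adjusted p of at most 0.0766, 0.0551 and 0.0678. ABCC and GSTU passed under 6, BZIP and MYB under 5 and LCR under 4, with exact adjusted p of at most 1, 0.502, 0.161, 0.27 and 0.317. With only the wider of 2 equal parts of the peaks the odds ratio of ABCC was 1.13, against 6.77 with all peaks.

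**Figure D5:**
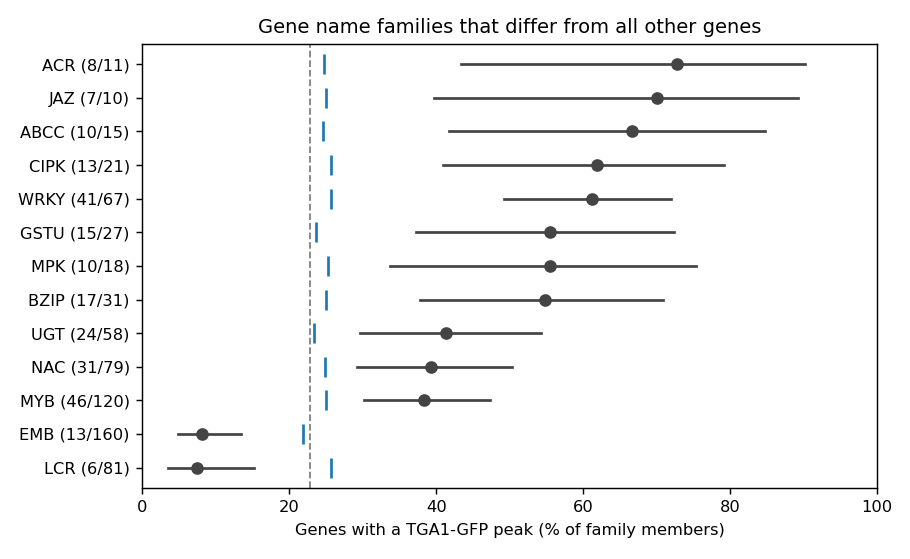
Share of the members of each gene name family with a TGA1-GFP peak (points, horizontal axis in percent) with 95% Wilson intervals, for the 13 families that differed from all other genes. The dashed line is 22.8% of all protein-coding genes and the ticks are means of random sets matched on flank length; EMB and LCR lie at 8.12 and 7.41%, the other families above the line.

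Of the 15 widest, 14 had midpoints outside the assignment zones. The widest of all, 4997 bp at place 113 (chromosome 1, 4576466 to 4581462), was assigned to AT1G13360. After the peak at TGA1 in width came a peak 4138 bp wide that overlapped ERF4 (AT3G15210), an ethylene response repressor, and a peak 4130 bp wide that overlapped WRKY29 (AT4G23550); their midpoints lay 1450 and 1793 bp outside these genes. A peak 3483 bp wide overlapped both LOG7 (AT5G06300), a cytokinin-activating enzyme, and its neighbour 2-Cys Prx B. A peak 3248 bp wide overlapped AOX1A (AT3G22370), the mitochondrial alternative oxidase, and a peak 2961 bp wide overlapped the proton pump gene AHA2 (AT4G30190). A peak 2972 bp wide overlapped both AT4G37550, the nearest gene at 1005 bp from its midpoint, and LBD39 (AT4G37540), a repressor of nitrate-responsive genes, at 1180 bp. Peaks 3466, 3543, 3301 and 2970 bp wide overlapped APY1 (AT3G04080), AT5G11090, AT2G32150 and AT3G60690. The other 3 overlapped no protein-coding gene: peaks of 3930, 3220 and 3144 bp were nearest to RAV1 (AT1G13260), AT1G78070 and NAC047 (AT3G04070).

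The first 15 peaks of the list shared 1 peak with the 15 widest, the 3543 bp peak at place 11 beside AT5G11090. The peak at place 1, 1560 bp wide (chromosome 5, 25805060 to 25806619), was assigned to AT5G64550 and MGT9. The next were at NAC102 (AT5G63790), a 699 bp peak at its end, and at AT1G22190, with 2093 bp. MKK9 (AT1G73500), a MAP kinase kinase, had a 1383 bp peak at place 12, GHS1 (AT3G27160) one of 1281 bp at place 8, and UGT73B3 (AT4G34131) and UGT73B2 shared a 670 bp peak at place 15.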

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

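The settings with the wider or the earlier of 2 equal parts of the peaks, any overlap of a peak with the zones, placements in the own bin and the salicylic acid set without WRKY genes were chosen after seeing the data. Of 35 checks of feature classes 34 kept their direction and side of the threshold; the excess of peaks far from genes reversed to 0.887 times chance with protein-coding genes alone. Of 113 checks of the gene sets 87 did, 5 were weaker, 16 stronger and 5 reversed. Values are odds ratios. A zone of 500 bp gave 4.92 (TGA), 2.46 (salicylic acid, no longer past the threshold) and 0.983 (phosphate, reversed), and 2000 bp gave 4.57 (sulfur). With each peak given to its nearest gene end, 11 sets passed, among them all 6 of the usual rule, and the newly passed were nitrate (13.9), TGA (5.53), phosphate (3.69), sulfur (11.1) and housekeeping (3.69). That setting reached far beyond 1000 bp and was not matched on flank length, which had a median of 6979 bp in the nitrate set. The whole gene with its flanks brought nitrate (4.22), TGA (4.60) and phosphate (4.3) past the threshold and reversed the glutaredoxins (0.959). The wider peaks brought in housekeeping (4.43). The earlier peaks brought in phosphate (5.21), ended the call of the cytokinin set (3.12) and reversed root hair genes (0.911). Any overlap brought in nitrate (3.23), TGA (4.35), phosphate (4.06) and sulfur (4.06), ended the call of the ammonium set (2.90) and reversed the glutaredoxins (0.907). Against flank-matched random sets the ratio was 1.89 for ammonium, no longer past the threshold, and 0.898 for glutaredoxins, reversed. Without its WRKY genes the salicylic acid set fell to 1.69. Families past the threshold numbered 22 by nearest gene end (9 of the 13 shared), 5 with the wider peaks (5 shared) and 6 with the earlier peaks (5 shared). Of 104 checks of the 13 families 68 were the same and 36 weaker, and of 415 checks of 83 named genes 359 gave the same answer; NRT2.1 and NLP7 had no peak in a zone of 500 bp. The cause of these changes was not tested. Not run were the planned tests of the TGACG motif, of 6-mers and of motif against strength, which need the genome sequence, the stronger part of the peaks by peak value and the summit in place of the midpoint, which need columns the list lacks, and classes by UTR, exon, intron and strand. No paired analysis and no leaving out of a replicate was possible because each antibody had 1 library. The unknown read depth limits all of these: a gene without a peak here was not shown to lack binding.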

Other observations

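All of the tests in this part were chosen after the result was seen. Genes that do not encode proteins carried fewer peaks than the 22.8% of protein-coding genes. A peak was assigned to 70 of 625 tRNA genes, 11.2% (95% interval 8.96 to 13.9%), 31 of 326 miRNA genes (9.51%), 18 of 287 snoRNA genes (6.27%), 11 of 82 snRNA genes (13.4%) and 76 of 3917 pseudogenes (1.94%), and to 725 of 3480 lncRNA genes (20.8%). The zone around a short gene is a little smaller, and neither this nor the density of peaks where these genes lie was corrected for. Compared with protein-coding genes by Fisher's exact test, all 6 classes passed an adjusted p of 0.05, with snRNA (0.0471) and lncRNA (0.00976) the closest to it.

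The densest 20 kb of the genome held 13 peaks (chromosome 5, 26901023 to 26920293, TAIR10) around LBD37, a repressor of nitrate-responsive genes, together with AT5G67430, NPY3 and ZF1. The highest number in 200 random placements was 12. Peaks lay closer together than chance over the whole list, as given below, so this comparison does not single out the locus. Another 4 places held 11 peaks each, which is below the highest number in the random placements, and 1 of them lay around ASL9 (chromosome 1, 5632269 to 5652465).

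In 6 fixed gene sets more members carried a peak than among other genes. Longer gene-free flanks as the whole cause are argued against for 5 of the 6 sets, which passed the threshold against random sets matched on flank length. In the glutathione transferase set that test did not allow for peaks shared by neighbouring genes. For the ammonium set the matched test gave an adjusted p of 0.18 (0.00101 to 0.18 over its alternatives, permutation test), so flank length and the set cannot be told apart there. Without its 6 WRKY genes, 7 of 21 genes of the salicylic acid set carried a peak against 4.98 in matched sets (permutation test, adjusted p = 0.502). These 6 genes were taken out after the data were seen and all carried a peak, so the share had to fall. Flank length stays open for the other members of that set. Heavy transcription as a cause stays open. Of 23 cytosolic ribosomal protein genes, 3 (13%, 4.54 to 32.1%) carried a peak, not different from other genes (Fisher's exact test, p = 0.328). Members of the 6 sets carried one in 70 of 116 cases (60.3%, Fisher's exact test against the ribosomal genes, p = 4.82e-05). That comparison cannot decide, because the 6 sets were picked for high shares in this same list and flank length was not matched. The 7 of 16 housekeeping genes with a peak (43.8%) could not be separated from the sets (Fisher's exact test, p = 0.28). Transcription was not measured here, and TGA1 binding as the biological explanation was not tested.

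The peak at TGA1 was 4142 bp wide at place 1538, where the 200 neighbouring list places had a median of 615 bp and at most 2112 bp. Per the labels, both libraries came from TGA1-GFP plants, so extra DNA copies of the transgene could add reads at this locus. The peak covered 26.6% of the gene. This cannot decide on copies of the whole gene, because the list holds called peaks and not read coverage. The IgG library would carry the same copies, and whether it served as the control is not known. Copies of only the sequence beside the gene could give the 3176 bp that lay outside it, and the list alone cannot exclude them. Binding of TGA1 beside its own gene was not tested apart from this.

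Peaks lay closer together than chance placed them. There were 1923 neighbouring pairs within 1000 bp, against 996 ± 27.0 (SD) and at most 1083 when peaks were placed at random within their own 1 Mb bin. Density at the scale of 1 Mb was therefore not enough, and density at finer scales was not tested. Keeping each peak also in its own feature class gave 1312 ± 27.2 and at most 1395, so the share of peaks in each class was not enough either. These placements did not keep the distance from the gene end, so the crowding of peaks close to gene ends stays open. Splitting of 1 broad region into several peaks by the peak caller was not tested, and neither was a biological explanation.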
